A study of Homo sapiens with 6 samples.

How the data were processed

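The series holds 6 RNA-seq libraries of A375 cells, an established human melanoma line that carries a mutant BRAF gene. Per the labels' protocols, the cells were starved for 2 h and then given 10 ng/mL of TGFB1, a ligand of the TGF-beta pathway, or its vehicle, 4 mM HCl with 1 mg/mL BSA, for a further 2 h. There were 3 TGFB1 and 3 Vehicle libraries. The series' design text calls them technical triplicates, so every p-value here measures only the spread between these libraries, not that between independent experiments. The labels name polyA RNA as the molecule, while the extraction protocol describes depletion of ribosomal RNA before fragmentation and reverse transcription. Transcripts without a poly(A) tail, such as RN7SL2 at a mean of 8103 CPM (counts scaled to the library total) and SNORD3A at 2825 CPM, were among the 15 most abundant.

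The deposited table holds raw read counts per gene for 58051 Ensembl gene IDs and carries no rows for unassigned reads. Per the submitters' processing notes, the tools were cutadapt, which trims reads, TopHat2 2.1, an aligner, and HTSeq, which counts reads per gene, with GRCh38 as the genome build. The annotation release, the counting mode and the strand setting are not given in the sources used here. Of 17 protein-coding genes with at least 99% of their exonic bases under exons of the other strand in GENCODE 29, 14 had 0 counts (82.4%), against 9.31% of those with no overlap. Counts of the 187 called genes that share exonic bases with an opposite-strand gene are therefore taken to rest mainly on their unshared exons. Antisense genes, whose unshared exons can lie inside a partner gene's introns, and multicopy genes are given as uncertain. Symbols were matched by gene ID and named 41445 of the 58051 rows. Coordinates are those of GENCODE 29 on GRCh38, which need not be the release used for counting.

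Library totals ran from 24713894 to 34895075 counts. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 16690, and scaled by TMM. The test was edgeR's quasi-likelihood F-test with robust dispersion (edgeR 4.0.16, R 4.3.3), with the group as the sole term. P-values were adjusted by Benjamini-Hochberg over all 16690 genes, with a threshold of 0.05. All adjusted p-values of genes come from this test unless another is named. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. Means ± SD are of CPM over 3 libraries.

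Before the data were examined, 24 gene lists were fixed, with 384 symbols, of which 382 matched a row; H3C2 and H3C3 did not. The 21 lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 21 lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, whereas fry tests a list against no change, so a list can pass one and not the other without contradiction. Of the 11 lists past the threshold with the preset correlation, 1 held with an estimated correlation, that of TGF-beta/SMAD feedback and direct target genes. Without Vehicle replicate 1, Vehicle replicate 3 or TGFB1 replicate 1, the lists past the threshold numbered 5, 7 and 7. With fry, 9 lists passed for movement in 1 direction and 17 for change in either direction. In 5 of the 10 lists not past the threshold, the median, the mean and the test differed in sign.

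The named genes follow a rule fixed with the lists. It takes the 12 largest log2 fold changes in each direction among genes past the threshold, with a mean of at least 1 CPM and no overlap between the libraries of the groups. It adds from each list up to 4 members with the smallest p, or the 2 most abundant where none passed, any member of the first 2 lists, and the ligand, receptors and SMADs of the pathway. This gave 108 genes, some of which are not reported here; others are said to be named after their values were seen.

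The alternatives fixed beforehand were DESeq2's size factors, upper-quartile scaling and total counts in place of TMM, no low-count filter, a filter of at least 50 counts in 3 libraries, removal of the 100 most abundant genes, a replicate block, DESeq2 1.42.0, limma-voom, glmTreat at 1.2-fold, a threshold of 0.01, and leaving out each library. limma-voom with sample quality weights was added after seeing the data.

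The gene test was tested on simulated data drawn from these libraries' means and dispersions, with 200 of 16690 genes changed. The low-count filter left 16311 of the simulated genes, and a changed gene dropped by it was scored as not recovered. It recovered 26% of those changed 1.25-fold, 62% at 1.5-fold, 68% at 2-fold and 90% at 4-fold, with 0 sign errors. Of its 136 calls, 13 (9.56%) were of unchanged genes, above the nominal 0.05. For camera, 6 of 100 unchanged lists and 10 of 10 lists raised 1.5-fold had an unadjusted p under 0.05. Members of those lists were drawn at random and simulated independently. The result therefore gives no error rate for lists whose members vary together. The estimated correlation of the real lists ran from -0.0565 (heat shock) to 0.741 (histone). No single-cell, read-level or pathway-database analysis was made.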

Results

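The data are counts of RNA-seq reads per gene in A375 melanoma cells, from 3 libraries of cells given TGFB1 for 2 h and 3 of cells given vehicle. Vehicle replicates 1, 2 and 3 held 24713894, 30864319 and 34374668 counts, and TGFB1 replicates 1, 2 and 3 held 32523299, 34895075 and 32458753. Genes with at least 1 count numbered 29097 in Vehicle replicate 3 and between 27104 and 28146 in the other 5 libraries. The first principal component, with 28.9% of the variance, separated the groups, and Vehicle replicate 1 lay farthest out on it (-37.1, against -13.4 and -8.25 for Vehicle replicates 2 and 3). TGFB1 replicates 1, 2 and 3 lay at 20.7, 17.7 and 20.4, so this component also holds a wide spread within Vehicle. The coefficient of variation between libraries beyond counting error was 0.0886 in Vehicle and 0.0609 with TGFB1. Pairs of libraries within a group differed by 5.01 to 24.9 times the counting variance, so none was a copy of another. The largest value, between Vehicle replicates 1 and 3, was above those of Vehicle replicate 3 with TGFB1 replicates 1, 2 and 3 (10.9, 14.3 and 11.8).

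The comparison asks which genes responded to TGFB1 in these melanoma cells within 2 h. SMAD7, whose protein blocks TGF-beta receptor signalling, rose from 9.29 ± 1.74 CPM (SD, n = 3) in Vehicle to 61.1 ± 3.49 CPM (SD, n = 3) with TGFB1, a log2 fold change of 2.70 ± 0.10 (SE). The secreted lipase inhibitor gene ANGPTL4 (log2 fold change 3.41), the transcriptional repressor gene BHLHE40 (3.29), TMEM100 (3.21), the homeobox gene DLX2 (2.89), the metalloprotease gene ADAMTS15 (2.54) and the cytokine gene IL11 (2.48) also rose. KCNJ2, which encodes an inward-rectifier potassium channel, fell from 15.9 ± 1.15 to 4.43 ± 0.872 CPM (SD, n = 3 each), a log2 fold change of -1.84 ± 0.14 (SE). IL10, SPRY1, the transcriptional co-regulator gene CITED2, the interferon-stimulated gene IFIT2, LURAP1L, the ligand gene BMP4, the neural crest transcription factor gene FOXD3 and the nuclear receptor gene NR4A2 fell, with log2 fold changes from -1.51 to -1.09.

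Of 16690 genes tested, 553 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 405 higher and 148 lower with TGFB1. At least 2-fold, 100 were higher and 15 lower. The median size of the log2 fold change was 0.51 among the higher genes and 0.41 among the lower ones. At an unadjusted p under 0.05 there were 2048. The libraries of the groups did not overlap for 549 of the 553, and for 16.5% of all tested genes, against 10% by chance. Without Vehicle replicate 3 the count was 923, 683 higher and 240 lower. Without TGFB1 replicate 1 it was 365, 264 of them higher, and without TGFB1 replicate 3 the lower genes numbered 97.

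Several of the largest changes are uncertain because of a copy or an antisense partner. KCNJ12 (log2 fold change 3.02) has a near-identical paralog, KCNJ18, and REXO1L1P (-1.31) is one copy of a multicopy family. SLC7A11-AS1 (-1.40) is antisense to SLC7A11, and MIR181A2HG (2.23) is annotated as antisense. SAMD11 rose (2.69), and its exons overlap in part those of NOC2L on the other strand. Such a partial overlap also holds for other genes named here, BHLHE40, ANGPTL4, KCNJ2, FOXD3, IFIT2, JUNB and JAG1 among them. The long noncoding RNA LINC01711 rose by 3.11 ± 0.44 (SE) on the log2 scale, and ENSG00000237070, annotated as antisense and so uncertain, fell by 1.61 on the log2 scale. Vehicle means were low for LINC01711 (0.221 CPM), SAMD11 (0.352), KCNJ12 (0.383), MIR181A2HG (0.545) and TMEM100 (0.692). With TGFB1, those of IL10 (0.691 CPM) and SPRY1 (0.829) were low. The sizes of these changes rest on few reads in 1 group. REXO1L1P lost its call without Vehicle replicate 3 (adjusted p = 0.265) and without TGFB1 replicate 1, 2 or 3 (0.121, 0.128 and 0.097), and with total-count scaling (0.056), DESeq2 (0.0745) and limma-voom (0.118). SLC7A11-AS1 lost it without Vehicle replicate 2 (0.0504). SPRY1 lost it without Vehicle replicate 2 (0.0528) or TGFB1 replicate 3 (0.0644), and BMP4 without TGFB1 replicate 3 (0.0583).

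**Figure D1:**
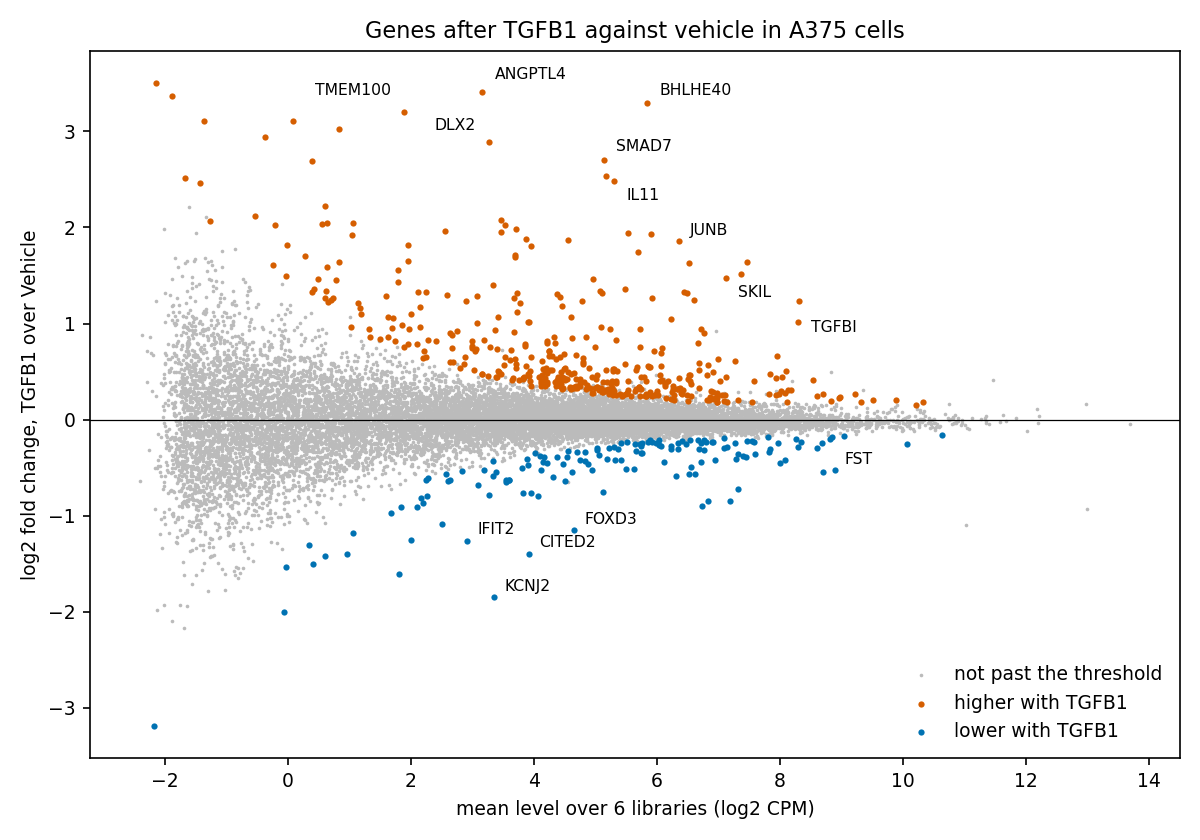
Log2 fold change, TGFB1 over Vehicle, against the mean level over 6 libraries (log2 CPM) for the 16690 genes tested except 3 not reported here; orange points are genes higher with TGFB1, blue points genes lower and grey points those not past the threshold. BHLHE40 lies at 3.29, SMAD7 at 2.70 and KCNJ2 at -1.84.

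TGF-beta/SMAD feedback and direct target genes rose nearly as a body: 15 of 16 tested members were higher, 0 were lower, and 15 were higher when adjusted over the list alone. SMAD7 lies on chromosome 18 at 48919853 to 48952052 and BHLHE40 on chromosome 3 at 4979116 to 4985323 (GRCh38). BHLHE40 rose from 10.6 ± 1.91 to 104.3 ± 9.58 CPM (SD, n = 3 each), and the AP-1 gene JUNB from 35.7 ± 1.00 to 129.2 ± 2.84 CPM. The corepressor gene SKIL (log2 fold change 1.47), KLF10 (1.93), RHOB (1.31), TGFBI (1.02) and TGIF1 (0.90) followed. The smallest rises were those of the ubiquitin ligase genes SMURF2 (0.47) and SMURF1 (0.34) and of the pseudoreceptor gene BAMBI (0.31). The exception was LDLRAD4, at 1.27 CPM in Vehicle, with a log2 fold change of -0.26 ± 0.37 (SE, adjusted p = 0.863). PMEPA1 rose from 57.5 ± 1.01 to 136.7 ± 15.2 CPM. Its antisense gene NKILA, uncertain for that reason, also rose (1.92, named after its value was seen). The list passed camera (adjusted p = 1.8e-30) and held with an adjusted p = 0.0185 with an estimated correlation.

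**Figure D2:**
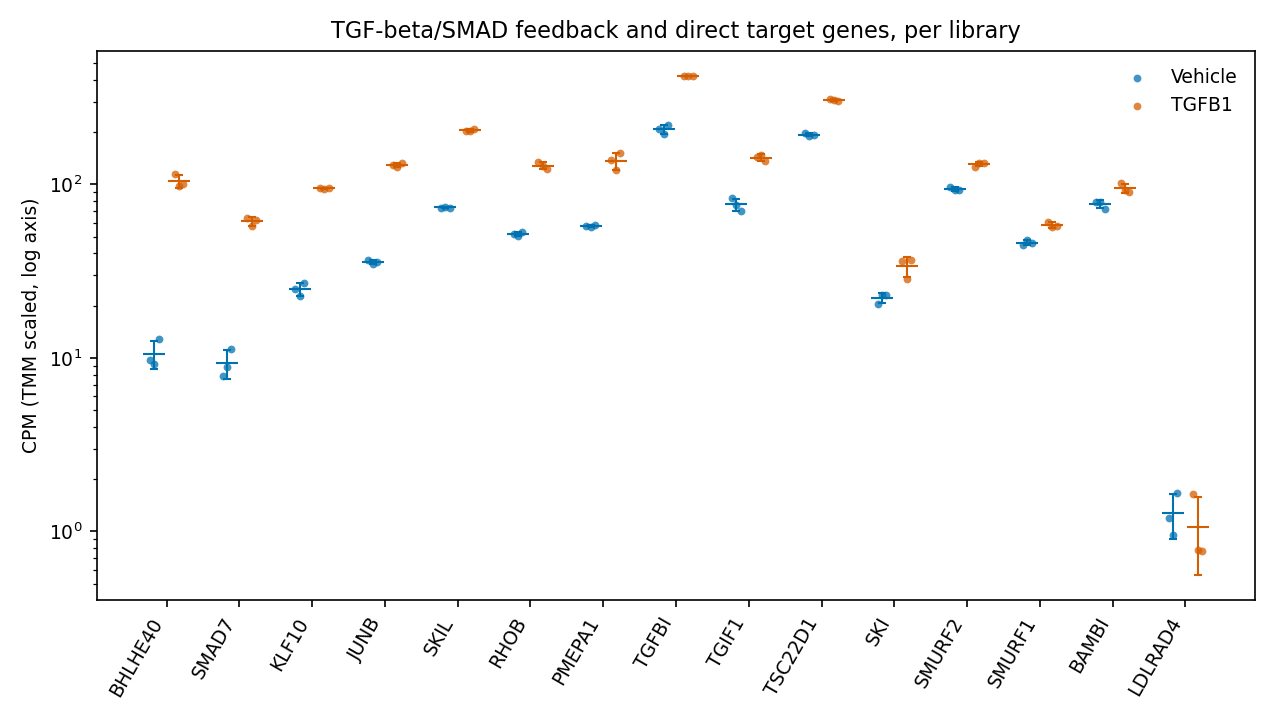
CPM on a log axis for 15 of the 16 TGF-beta/SMAD feedback and direct target genes; points are libraries, 3 Vehicle (blue) and 3 TGFB1 (orange), horizontal marks are means and bars are SD. The groups stand apart in each gene shown except LDLRAD4, where they overlap near 1 CPM.

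The receptors and SMADs of the pathway were themselves expressed in both groups. TGFBR1 stood at 102.3 ± 1.83 CPM in Vehicle and 97.1 ± 3.85 CPM with TGFB1, TGFBR2 at 41.9 ± 1.54 and 48.8 ± 1.46 CPM, SMAD2 at 163.1 ± 9.64 and 155.2 ± 0.297 CPM and SMAD4 at 57.4 ± 3.28 and 61.2 ± 3.53 CPM (SD, n = 3 each). None of these passed the test (adjusted p = 0.646, 0.0801, 0.658 and 0.644), nor did TGFB1 itself (log2 fold change 0.25, adjusted p = 0.52). TGFBR2 passed without Vehicle replicate 3 (adjusted p = 0.0338). Of 19 tested pathway components, the latent TGF-beta binding protein genes LTBP3 (0.54) and LTBP2 (0.84) and the transducer gene SMAD3 (0.30) rose. FST, which encodes the activin antagonist follistatin, fell from 559.1 ± 9.0 to 388.7 ± 1.66 CPM. Adjusted over the list alone, 4 were higher and 1 lower. The list did not pass (adjusted p = 0.414, and adjusted p = 0.561 with an estimated correlation). SMAD3 lost its call without Vehicle replicate 1 (0.133) or TGFB1 replicate 2 (0.0518) or 3 (0.161), and LTBP2 without Vehicle replicate 2 (0.258) or TGFB1 replicate 1 (0.237) or 2 (0.2), and with total-count scaling (0.0527), DESeq2 (0.0849) and limma-voom (0.0672).

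Of 14 tested BMP pathway and ID genes, 3 rose and 1 fell, and 6 were higher and 2 lower adjusted over the list alone. The risers were the helix-loop-helix inhibitor genes ID1 (26.0 ± 2.47 to 49.6 ± 4.53 CPM, log2 fold change 0.94), ID3 (0.75) and ID2 (0.72), and BMP4 fell (-1.18). The list passed camera (adjusted p = 0.00648), a call lost at adjusted p = 0.364 with an estimated correlation and at 0.0719 without Vehicle replicate 1. ID2 lost its call without TGFB1 replicate 1 (0.126), TGFB1 replicate 2 (0.0867) or Vehicle replicate 3 (0.0553), and BMP4 without TGFB1 replicate 3 (0.0583).

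Immediate early and AP-1 genes rose in part. Of 23 tested members 9 were higher and 1 was lower, with the same counts adjusted over the list alone. FOSB (log2 fold change 2.02), the stress-response gene ATF3 (1.34), JUN (1.26) and FOSL2 (1.07) rose, and NR4A2 fell (-1.09). The list passed camera (adjusted p = 0.000199) but not with an estimated correlation (adjusted p = 0.367 with an estimated correlation). Genes read as output of the MAPK/ERK pathway went both ways: 3 of 15 rose and 5 fell, and 4 and 5 did adjusted over the list alone. The feedback genes SPRY2 (0.51) and SPRY4 (0.75) rose, while SPRY1 (-1.42) and the ERK phosphatase genes DUSP4 (-0.45) and DUSP6 (-0.36) fell. That list did not pass (adjusted p = 0.881, and adjusted p = 0.929 with an estimated correlation), and its direction was down by camera and up by fry. SPRY1 lost its call without Vehicle replicate 2 (0.0528) or TGFB1 replicate 3 (0.0644).

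Of 22 tested YAP/TEAD target genes 4 rose and 1 fell, and 7 and 1 did adjusted over the list alone. The coagulation initiator gene F3 rose from 6.02 ± 0.586 to 19.8 ± 0.500 CPM (SD, n = 3 each), and AMOTL2 (log2 fold change 0.71), the matricellular gene CCN2 (0.65) and FOXF2 (0.94) rose as well. IGFBP3, named after its value was seen, fell (-0.23). The list passed camera at an adjusted p = 0.0254, a call lost at adjusted p = 0.556 with an estimated correlation, at 0.247 without Vehicle replicate 1 and at 0.0725 without TGFB1 replicate 3.

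Of 27 tested extracellular matrix, integrin and protease genes 4 rose and 0 fell, and 8 rose and 1 fell adjusted over the list alone. They were the anchoring fibril collagen gene COL7A1 (3.48 ± 0.120 to 8.53 ± 0.234 CPM), ITGA5 (log2 fold change 0.25), TIMP1 (0.22) and the urokinase receptor gene PLAUR (0.27). As a list they passed camera (adjusted p = 0.0212), a call lost at adjusted p = 0.383 with an estimated correlation, at 0.129 without Vehicle replicate 1, 0.055 without Vehicle replicate 3 and 0.195 without TGFB1 replicate 1. ITGA5 lost its call without TGFB1 replicate 1 (0.0684). TIMP1 lost it without Vehicle replicate 1 (0.073), Vehicle replicate 2 (0.123) or TGFB1 replicate 1 (0.212). PLAUR lost it without Vehicle replicate 2 (0.161), Vehicle replicate 3 (0.0811), TGFB1 replicate 1 (0.071) or TGFB1 replicate 2 (0.13).

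Among 11 tested transcription factor and adhesion genes of the epithelial-mesenchymal transition, SNAI1, which encodes the repressor SNAIL, rose from 5.24 ± 1.38 to 21.02 ± 2.43 CPM (SD, n = 3 each). VIM, the vimentin gene, rose by 0.16 on the log2 scale from 1117 ± 43.2 CPM, and TWIST1 fell (-0.43). Adjusted over the list alone, 3 rose and 3 fell. The list did not pass (adjusted p = 0.87, and adjusted p = 0.929 with an estimated correlation), and its median (-0.03) and mean (0.13) differed in sign. VIM lost its call with upper-quartile scaling (0.0795) and without any library but Vehicle replicate 3 (0.111 to 0.239).

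Of 8 tested Notch pathway genes 2 rose and 0 fell, and 3 rose adjusted over the list alone. JAG1, which encodes a Notch ligand, rose from 44.8 ± 1.53 to 139.0 ± 6.19 CPM and the repressor gene HES1 from 23.8 ± 1.61 to 80.1 ± 4.68 CPM (SD, n = 3 each). Camera gave an adjusted p = 0.00291, lost at adjusted p = 0.364 with an estimated correlation and at 0.217 without Vehicle replicate 1.

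Cytokine, chemokine and NF-kB genes moved in both directions, 4 of 20 up and 4 down, or 9 and 6 adjusted over the list alone. IL11 rose from 11.99 ± 0.725 to 67.2 ± 1.55 CPM (SD, n = 3 each), and the cytokine gene LIF (log2 fold change 1.95), the chemokine gene CCL2 (1.30) and the angiogenic factor gene VEGFA (1.05) rose with it. BIRC3 fell (-0.63), as did CXCL1 (-0.63), PTGS2 (-0.63) and CXCL8 (-0.42), named after their values were seen. Camera gave an adjusted p = 0.0342 upward, lost at adjusted p = 0.535 with an estimated correlation. It was also lost without Vehicle replicate 1 (0.0557), 2 (0.221) or 3 (0.122) and without TGFB1 replicate 1 (0.118) or 2 (0.211), and at 0.0622 with no low-count filter.

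Of 23 tested interferon-stimulated genes, IFIT2 fell from 10.6 ± 1.10 to 4.42 ± 0.269 CPM and IFIT3 from 34.1 ± 2.07 to 24.8 ± 1.58 CPM (SD, n = 3 each); 0 rose, and 3 fell adjusted over the list alone. Camera gave an adjusted p = 0.0342 downward, lost at adjusted p = 0.383 with an estimated correlation. It was also lost without Vehicle replicate 2 (0.0533), Vehicle replicate 3 (0.101) or TGFB1 replicate 3 (0.311) and at 0.0622 with no low-count filter. The adjusted p of fry, which tests a list against no change, was 0.0538. Of 17 antigen presentation genes 1 rose, CD74, the invariant chain gene (log2 fold change 0.21), also the single call adjusted over the list alone. The list did not pass (adjusted p = 0.275, and adjusted p = 0.535 with an estimated correlation). CD74 lost its call with total-count scaling (0.0895), without Vehicle replicate 1 (0.146) or 2 (0.149) and without TGFB1 replicate 1 (0.157) or 2 (0.0603).

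Of 15 tested genes of melanocyte identity 1 fell and 0 rose. MITF, the melanocyte master regulator, fell from 62.7 ± 3.02 to 53.5 ± 2.01 CPM (SD, n = 3 each), also the single call adjusted over the list alone. The list did not pass (adjusted p = 0.977, and adjusted p = 0.977 with an estimated correlation), and its median (-7e-04) and mean (0.04) differed in sign. For change in either direction fry gave an adjusted p = 0.000127, but 17 of the 21 lists passed that test, so it does not set this list apart. SOX10, named after its value was seen, was listed at 0 counts in all 6 libraries. MITF lost its call with limma-voom (0.0537) and no low-count filter (0.0854), and without Vehicle replicate 1 (0.107), Vehicle replicate 2 (0.229), TGFB1 replicate 1 (0.208) or TGFB1 replicate 3 (0.205). Of 14 genes of dedifferentiated melanoma BIRC3 fell and 0 rose, while 3 rose and 1 fell adjusted over the list alone. That list did not pass (adjusted p = 0.414, and adjusted p = 0.737 with an estimated correlation), and its median (0.05) and mean (-0.02) differed in sign.

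Among 10 cyclin-dependent kinase inhibitor and growth arrest genes GADD45B rose from 8.27 ± 1.35 to 19.2 ± 0.632 CPM (SD, n = 3 each) and CDKN1C rose (log2 fold change 0.38), while CDKN1B, which encodes p27, fell (-0.44). Adjusted over the list alone 2 rose and 2 fell, and the list did not pass (adjusted p = 0.87, and adjusted p = 0.929 with an estimated correlation). CDKN1C lost its call with DESeq2 (0.0565) and without any library but Vehicle replicate 2 (0.0592 to 0.169). Of 20 proliferation genes 1 rose, the mitotic kinase gene PLK1 (0.26), also adjusted over the list alone. That list did not pass (adjusted p = 0.87, and adjusted p = 0.929 with an estimated correlation), and its median (-0.02) and mean (0.01) differed in sign. PLK1 lost its call with total-count scaling (0.112), without Vehicle replicate 1 (0.0815) or 2 (0.269) and without TGFB1 replicate 1 (0.192) or 3 (0.18).

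Of 18 sterol synthesis genes 2 fell and 0 rose, and 4 fell adjusted over the list alone. Camera gave an adjusted p = 0.0207, lost at adjusted p = 0.364 with an estimated correlation, at 0.103 without Vehicle replicate 3, at 0.071 without TGFB1 replicate 1 and at 0.0622 with no low-count filter. Of 14 heat shock and unfolded protein response genes the heme oxygenase gene HMOX1 rose (log2 fold change 0.69) and HSPA1A fell (-0.43), with 1 and 3 adjusted over the list alone. The list did not pass (adjusted p = 0.68, and adjusted p = 0.737 with an estimated correlation) by camera, and fry's test against no change gave an adjusted p = 0.0381. HSPA1A, a near-identical copy of HSPA1B and so uncertain, lost its call with DESeq2 (0.0743), limma-voom (0.0576), total-count scaling (0.0616) and no low-count filter (0.0608), and without any library but Vehicle replicate 3 (0.0615 to 0.263).

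Of 20 replication-dependent histone genes 1 fell, H2AC20 (log2 fold change -0.17), 0 rose, and 4 fell adjusted over the list alone. By camera the list was lower (adjusted p = 0.00288), a call lost at adjusted p = 0.624 with an estimated correlation, at 0.155 without Vehicle replicate 1 and at 0.144 without TGFB1 replicate 1. The adjusted p of fry's test against no change was 0.395. H2AC20 lost its call with no low-count filter (0.119) and without Vehicle replicate 1 (0.261), Vehicle replicate 2 (0.134), TGFB1 replicate 1 (0.387) or TGFB1 replicate 3 (0.241). Genes of the same histone family can be near-identical to one another, so single members are uncertain.

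Of 13 mitochondrially encoded genes 7 fell and 0 rose, and 8 fell adjusted over the list alone. The complex I genes MT-ND5 (95.5 ± 10.3 to 63.5 ± 4.42 CPM), MT-ND6 (21.3 ± 0.630 to 12.3 ± 2.05 CPM), MT-ND4 (log2 fold change -0.51) and MT-ND1 (-0.59) were among them. So were MT-ATP6 (-0.46) and MT-CYB (-0.41), of neither complex I nor complex IV. The complex I genes MT-ND3 (-0.09, adjusted p = 0.81) and MT-ND4L (-0.49, adjusted p = 0.0615) did not pass. Nor did the complex IV genes MT-CO1 (0.27), MT-CO2 (-0.00) and MT-CO3 (0.26). MT-ATP6, MT-CYB, MT-ND3, MT-ND4L and the MT-CO genes were named after their values were seen. By camera the list was lower (adjusted p = 7.04e-05), a call lost at adjusted p = 0.458 with an estimated correlation; fry's test against no change gave an adjusted p = 0.0981. The mitochondrial ribosomal RNA MT-RNR2 varied between libraries from 3931 to 17130 CPM and did not pass (adjusted p = 0.611).

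**Figure D3:**
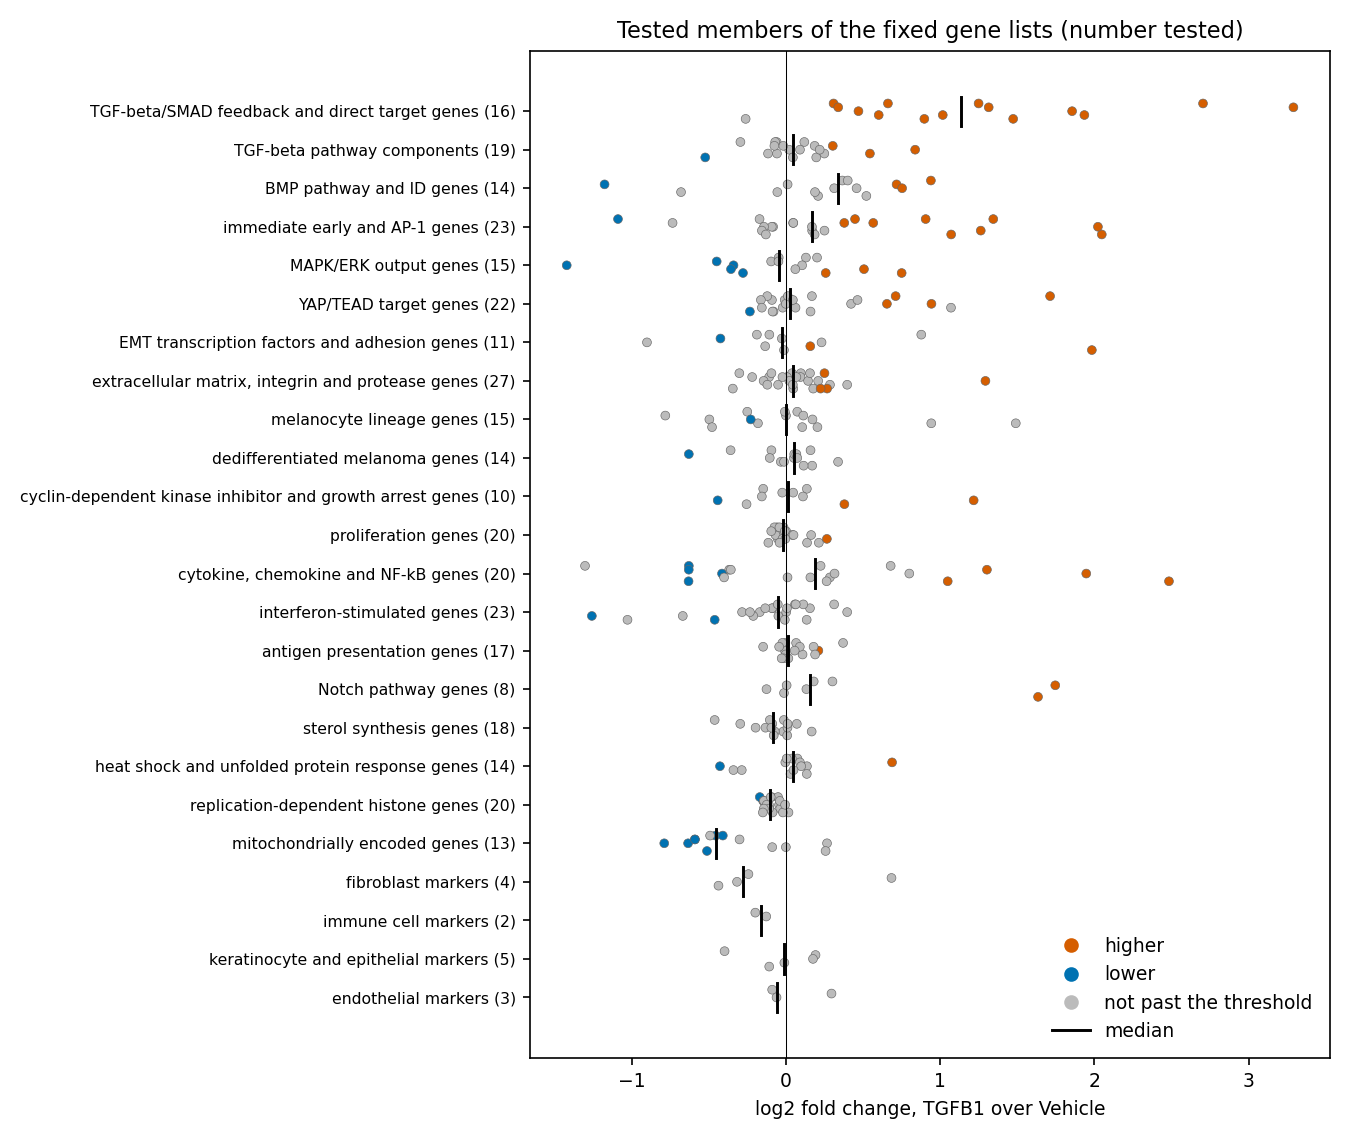
Log2 fold change, TGFB1 over Vehicle, of the tested members of the 24 gene lists except 3 genes not reported here; orange members were higher, blue members lower and grey ones not past the threshold, and black bars are medians of all tested members. The median of the TGF-beta/SMAD feedback and direct target genes is 1.13, and other medians lie between -0.46 and 0.34.

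Markers of other cell types were low or did not differ. Of the fibroblast, immune and endothelial markers 4, 2 and 3 were tested, too few for a test of the list, and 0 passed over all genes tested by edgeR. Adjusted over the list alone, 1 fibroblast marker was higher and 1 lower, and 0 of the others passed. LUM stood at 9.70 ± 0.836 CPM in Vehicle and 7.76 ± 0.821 with TGFB1 (SD, n = 3 each), PDGFRA at 3.26 and 2.40 CPM, LYZ at 6.63 and 6.05 CPM, CSF1R at 0.332 and 0.288 CPM, KDR at 15.6 and 14.7 CPM and TEK at 0.631 and 0.621 CPM. Of 5 keratinocyte and epithelial markers 0 passed, also adjusted over the list alone, with KRT18 at 203.1 ± 4.18 and 201.5 ± 6.53 CPM and KRT10 at 44.5 ± 7.99 and 51.0 ± 3.86 CPM. That list did not pass (adjusted p = 0.87, and adjusted p = 0.929 with an estimated correlation). KRT10 passed without Vehicle replicate 3 (adjusted p = 0.00294).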

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

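The count of 553 changed genes kept its size within 1.5 times under every alternative except 3. It was 220 with glmTreat at 1.2-fold, whose stricter null shows the cause, and over the fits that each leave out 1 library it ran from 365 (without TGFB1 replicate 1) to 923 (without Vehicle replicate 3), where the cause was not tested. Over the same fits the higher genes ran from 264 to 683, the lower genes from 97 to 240 and the gene lists past the threshold from 5 to 10. Of the 553 genes, 424, 370 and 509 were also called without Vehicle replicate 1, 2 and 3. Without TGFB1 replicate 1, 2 and 3, 361, 431 and 369 were. With DESeq2 (519 calls) 498 were shared, with limma-voom (517) 494 and with sample quality weights (636) 535. The quality weights were chosen after seeing the data and ended the calls of REXO1L1P (0.137) and LTBP2 (0.0675). Upper-quartile scaling gave 68.3% higher calls against 73.2%. Nothing says that replicate numbers pair the libraries: the deviations of same-numbered libraries correlated at -0.0296, 0.0418 and 0.00761 for replicates 1, 2 and 3, those of replicate 2 alone correlated best with their own number across the groups, and the replicate block called 601 genes, 533 of them shared. With the block 7 lists passed, against 11. It ended the calls of YAP/TEAD target genes (0.0529), extracellular matrix genes (0.0872), cytokine genes (0.102) and interferon-stimulated genes (0.185), and of the named genes REXO1L1P (0.0644), LTBP2 (0.0547) and HSPA1A (0.05).

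With an estimated correlation, 1 list passed. The adjusted p was 0.364 for the BMP, Notch and sterol lists, 0.367 for immediate early genes, 0.556 for YAP/TEAD targets, 0.383 for extracellular matrix and interferon-stimulated genes, 0.535 for cytokines, 0.624 for histones and 0.458 for mitochondrially encoded genes. fry tests a list against no change, not against the other genes, so its result is not the same call: it did not pass interferon-stimulated (0.0538), histone (0.395) and mitochondrially encoded genes (0.0981), which camera passed, and passed the heat shock list (0.0381), which camera did not. With no low-count filter the cytokine, interferon and sterol lists each stood at 0.0622. Without 1 library, the adjusted p ran from 0.00274 to 0.0719 for BMP genes, 0.00874 to 0.247 for YAP/TEAD targets, 0.0157 to 0.195 for extracellular matrix genes, 0.0104 to 0.221 for cytokines, 0.00583 to 0.217 for Notch genes, 0.000106 to 0.155 for histones, 0.0324 to 0.311 for interferon-stimulated genes and 0.0167 to 0.103 for sterol genes. The cause of these losses was not tested.

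There were 35 changes of direction, 16 for lists and 19 for genes, none of them past the threshold; their cause was not tested. For lists, the adjusted p was 0.949 with upper-quartile scaling, 0.95 with no low-count filter and 0.994 with fry for melanocyte genes, 0.797 (no low-count filter) for proliferation genes, 0.919 (no low-count filter) for keratinocyte markers, 0.787 (at least 50 counts) and 0.949 (fry) for MAPK/ERK genes, and 0.931 for EMT genes without the 100 most abundant genes. The next ranges of the adjusted p cover every fit without 1 library, including those in which the direction was kept. They were 0.526 to 0.941 for EMT, 0.688 to 0.95 for MAPK/ERK and 0.804 to 0.961 for melanocyte genes. For keratinocyte, kinase inhibitor and proliferation genes they were 0.337 to 0.941, 0.419 to 0.948 and 0.593 to 0.966. For genes, the log2 fold change was 0.00066 for KRT18 with no low-count filter, 0.10 for TEK with the block, 0.13 for TEK and 0.0061 for CSF1R with limma-voom, and 0.24 and 0.15 with quality weights. Without 1 library it ran from -0.17 to 0.039 for ENG, -0.63 to 0.23 for CSF1R, -0.073 to 0.12 for TGFB2, -0.031 to 0.013 for KRT18, -0.45 to 0.54 for TEK, -0.085 to 0.045 for LTBP1 and -0.20 to 0.20 for ACVRL1. Of 84 named genes past the threshold 66 kept their call in every alternative run, 9 lost it in an alternative other than leaving out a library, and 2 of 24 others gained it. With 3 libraries per group, 26% of the smallest simulated changes were recovered, and depth was not varied apart from dispersion or the number of libraries.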

Other observations

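Several genes outside the fixed lists changed as clearly as those in them. They are named here after their values were seen, were not tested as groups and were not carried through the alternatives. The T-box repressor gene TBX3 rose by 1.64 ± 0.05 (SE) on the log2 scale from the edgeR fit (adjusted p = 8.89e-22), and RUNX3 (1.88), SOX4 (1.24) and DLX1 (0.86) rose too. Other developmental transcription factor genes fell: SOX2 (log2 fold change -0.75, adjusted p = 9.92e-09), NEUROG2 (-0.91), ISL1 (-0.79) and MEIS1 (-0.68). Of the tests that follow, those of another cell type, of general mitochondrial yield, of the FOXO and glucocorticoid lists, of the SOX10 overlap and of the library splits were chosen after values they bear on had been seen.

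The Wnt ligand gene WNT9A (log2 fold change 2.08 ± 0.13, SE) and DACT1 (1.69) rose, and the secreted Wnt inhibitor gene DKK1 fell (-0.90 ± 0.06, SE). The genes of the glycolytic regulator enzymes PFKFB3 (0.80) and PFKFB4 (0.83) rose. Of the glucose transporter genes SLC2A1 (0.26) and SLC2A12 (2.03) rose and SLC2A3 fell (-0.45, adjusted p = 1.7e-06), and TXNIP, which encodes a thioredoxin-binding protein, fell (-0.84, adjusted p = 7.14e-13).

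Vehicle replicate 3 detected more genes than the other libraries. Thinned to 24713894 counts it still detected 611 more than the highest of the other 5, which argues against depth. No gene under 0.1 CPM elsewhere exceeded 0.698 CPM there, against a limit of 5 CPM set for an abundant transcript of another cell type. This argues against a large share of such RNA. A small share could stay below that limit, so the test cannot decide on it. Its excess reads per exonic Mb were 1.28 times as high in silent genes inside expressed genes as in silent genes over 10 kb from any (95% bootstrap interval 0.982 to 1.59), which is in line with genomic DNA as a candidate source. Unspliced RNA cannot be told apart from it, since that interval spans 1.5, and no biological explanation was tested.

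The fall of mitochondrially encoded genes was uneven. The mean log2 level of 7 MT-ND transcripts fell against that of 3 MT-CO transcripts (difference -0.718, pooled SD 0.15, n = 3 each). This argues against a lower yield of all mitochondrial RNA. The fall was not one of complex I alone: MT-ND3 hardly moved (log2 fold change -0.09), and MT-ATP6 (-0.46) and MT-CYB (-0.41) fell. The ribosomal RNAs MT-RNR2 (log2 fold change -0.928) and MT-RNR1 (-1.1) were lower with TGFB1, but both were highest in Vehicle replicate 1. Neither passed the edgeR test (adjusted p = 0.611 and 0.529). The summed counts of MT-ND genes and 214 nuclear copies also fell (-0.536, pooled SD 0.124). That sum is mostly MT-ND reads, at 249.2 CPM in Vehicle against 4.64 CPM for the copies. The copies alone did not rise (-0.288, pooled SD 0.378), which argues against reads being counted for the copies instead. Reads that align to both and were counted for neither would not show, so their loss was not tested. A response to TGFB1 may remain, as a hypothesis found on these data, but the list's call was lost with an estimated correlation (adjusted p = 0.458) and other technical explanations were not tested.

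SOX10 was listed at 0 counts in all 6 libraries, although MITF stood at 58.0 CPM and ERBB3 at 275.2 CPM. Protein-coding genes with at least 99% of their exonic bases under opposite-strand exons were at 0 for 14 of 17 (82.4%), against 9.31% of those with none, in line with reads over exons of both strands being discarded. For SOX10 itself the overlapped share is 2.4% in GENCODE 29, which argues against such loss under that annotation; the release used for counting is not given in the sources used here. Among 839 silent genes of similar length 12.8% were at 0. This shows that a silent gene can be listed at 0, not that SOX10 is silent. A lack of SOX10 transcript therefore stays open and was not shown. SOX10 (37970686 to 37987422 on chromosome 22) lies inside the span of POLR2F (37952607 to 38041915), which is on the other strand. POLR2F had 478 counts over the 6 libraries, and whether reads of either gene were lost at this locus was not tested further.

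It was asked whether CDKN1B, CITED2, KLF9 and TXNIP, which fell, could reflect FOXO targets as a group. In a list of other FOXO targets, 19 tested, the median log2 fold change was 0.0208 (95% bootstrap interval -0.123 to 0.149, camera adjusted p = 0.683), with 0 higher and 2 lower, PDK4 (-0.52) and IRS2 (-0.23). For DDIT4, SGK1 and KLF9 the same was asked of glucocorticoid receptor targets, and 18 other targets had a median of 0.0673 (-0.0511 to 0.205, camera adjusted p = 0.683), with ERRFI1 lower (-0.25) and CDKN1C higher (0.38). Members called lower were found in both lists although both medians were positive, so neither median decides and both questions stay open. Single members of both lists had been seen before the lists were tested.

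The 6 libraries can be split 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one has TGFB1 and Vehicle libraries on both sides, so a difference between the groups widens its spread and lowers its calls. Few calls in those splits are therefore no measure of chance. The real split called 553 genes (405 higher, 148 lower) and the highest of the other splits called 1. At least 2-fold it called 115 against 0, and 11 lists passed against at most 4; 1 of the 10 splits, the real one, reached each real value.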
